A study of Homo sapiens with 14 samples.

How the data were processed

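RNA was taken from each sample and polyA libraries were sequenced, per the labels' protocols, giving 14 libraries in 5 groups: NU-DHL1 IgM (n = 3), NU-DHL1 IgG1 WT (n = 3), NU-DHL1 IgG1 W375* (n = 3), WSU-FSCCL IgG1 WT (n = 2) and WSU-FSCCL IgG1 W375* (n = 3). Class-switched cells were made with Cas9 and sorted by flow cytometry, and the stop codon was written into IGHG1 by prime editing before 15 weeks of culture, per the labels' protocols. Groups and replicate numbers were taken from the labels.

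The authors aligned reads with HISAT2 to GRCh38, per the submitters' processing notes; versions, the counting tool and the strand setting are not given in the sources used here. The deposited table holds 58735 genes with 28 columns of values, 1 column of raw counts and 1 of FPKM per library, all of which were read. The counts were deposited as whole numbers without normalization. The FPKM values were deposited by the authors as the count scaled to the listed gene length and to a library total that exceeds the table's own, since the table holds 78.4 to 93.3% of it. All 58735 gene identifiers, with their chromosome, start and end, were the same as in GENCODE 29, and coordinates are given on GRCh38 as deposited. Reads of antisense or overlapping genes cannot be told apart without a stated strand setting.

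Total counts per library were 33258701, 34367694 and 35923426 in NU-DHL1 IgM libraries 1 to 3, 30170723, 32498591 and 38311150 in IgG1 WT, 33539266, 37751824 and 43785197 in W375*, and from 32557083 to 42681167 in WSU-FSCCL. Immunoglobulin genes took 0.0903 to 0.296% of the counts and TMM factors ran from 0.900 to 1.09. A group with 0 counts was given a floor of 3 counts over the group.

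Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM, glmQLFit and glmQLFTest), with Benjamini-Hochberg adjustment and a threshold of 0.05. The 9 NU-DHL1 libraries were fitted together for 3 comparisons (IgG1 WT against IgM, W375* against IgG1 WT, W375* against IgM), the 5 WSU-FSCCL libraries for W375* against WT, and all 14 libraries for the difference of the W375* effect between lines. Standard errors were taken from the quasi-likelihood F statistic. CPM values are TMM-scaled. In all, 35 gene lists were fixed by hand, and those with at least 3 tested members (33 lists) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists; none of the camera calls in any comparison held with an estimated correlation. NK cell markers (2 tested members) and erythroid markers (1) had too few. Fry tested whether the genes of a list moved, on balance, one way. Comparisons, tests, lists and the rule for named genes were fixed before the data were examined.

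Named genes were IGHM, IGHD and IGHG1; in each comparison the 6 protein-coding genes with the largest rise and the 6 with the largest fall among those past the threshold with a mean of at least 5 CPM over both groups and no overlap between groups; the 3 largest called members of each list that passed and the 2 largest of another list with at least 5 called members; and the 4 largest each way for the difference between lines and for the overlap of the lines. Immunoglobulin variable segments were left out of the choice of 6 by size, but not of the 4 largest for the difference between lines, where IGKV4-1 is one. In all, 1 gene that met this rule is not reported here.

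Comparisons that share libraries were set beside 30 simulations of unchanged groups and beside the overlap of independent lists. The fit was tested on simulated data with 200 genes changed by known folds in the real mean levels and library sizes. For IgG1 WT against IgM it recovered 59.1% of 4-fold, 8.96% of 2-fold and 0% of 1.5-fold changes among 15418 genes, with 2 false calls among 47. The 4-fold recovery was 72.7% for W375* against IgG1 WT (4 false of 58 calls, 15447 genes), 72.7% for W375* against IgM (0 false of 58, 15428 genes) and 68.2% for WSU-FSCCL (5 false of 59, 15577 genes), and none of the 1.5-fold changes was recovered in these either.

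Alternatives were DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1), RLE factors, TMM without immunoglobulin genes, no filter, a mean CPM of at least 5, other sets of libraries in the fit, a replicate block, a log2 fold change of at least 1, and leaving out each library. Added after the data were seen were the G2/M level as a covariate, fits without NU-DHL1 IgG1 WT libraries 1 and 2, fits without NU-DHL1 W375* libraries 1 and 2, and fits without genes at least 20 times higher in WSU-FSCCL. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Isoforms, the share of edited alleles and sequence variants were left out, since the table holds no reads.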

Results

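Transcript levels were measured by polyA RNA sequencing in 14 libraries from 2 established human B cell lymphoma lines, NU-DHL1 and WSU-FSCCL. NU-DHL1 cells that carried their original IgM receptor (n = 3 libraries) were set beside cells whose heavy chain had been switched to IgG1 by Cas9 cutting at the IgM and IgG1 switch regions, with the tail of the IgG1 receptor intact (IgG1 WT, n = 3) or with a W375* stop codon made in IGHG1 by prime editing (IgG1 W375*, n = 3). WSU-FSCCL gave 2 IgG1 WT and 3 IgG1 W375* libraries and no IgM library. The stop codon lies near the start of the cytoplasmic tail of membrane IgG1. Edited cells had been kept in culture for 15 weeks, over which W375* cells outgrew WT cells to more than 95% of the NU-DHL1 and more than 77% of the WSU-FSCCL population. Total counts per library ran from 30170723 to 43785197. The labels do not say whether replicates were separate cultures, so every p-value measures only the spread between these libraries.

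IGHM and IGHD, the constant genes of the IgM and IgD heavy chains, were abundant in NU-DHL1 IgM cells and low after switching, while IGHG1, the edited gene, moved the other way. IGHD (ENSG00000211898, GRCh38 chromosome 14, 105836765 to 105845678) fell from 230 ± 81.9 to 4.83 ± 0.932 CPM (mean ± SD, n = 3). IGHM (ENSG00000211899, chromosome 14, 105851705 to 105856218) fell from 1239 ± 576 to 274 ± 77.2 CPM, and so kept 21.7% of all heavy chain constant counts in IgG1 WT cells, against 71.0% in IgM cells. IGHG1 (ENSG00000211896, chromosome 14, 105736343 to 105743071) rose from 33.4 ± 19.9 to 599 ± 257 CPM. The log2 fold changes were -5.56 for IGHD (adjusted p = 0.000141), -2.17 for IGHM (adjusted p = 0.0203) and 4.18 for IGHG1 (adjusted p = 0.00189) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The IGHM call ended without IgM library 1 or IgG1 WT library 1 or 2, whereas IGHD and IGHG1 kept theirs without any single library. IGHG1 shares long stretches with IGHG2, IGHG3 and IGHG4, and how the authors counted shared reads is not stated, so levels of single IGHG genes are uncertain.

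IGHG1 transcripts stayed abundant in W375* cells, at 282 ± 61.2 CPM (n = 3) in NU-DHL1 and 544 ± 101 CPM (n = 3) in WSU-FSCCL. Membrane and secreted transcripts were counted together. Against IgG1 WT, the IGHG1 log2 fold change was -1.13 in NU-DHL1 (adjusted p = 0.353, edgeR quasi-likelihood, Benjamini-Hochberg) and 0.28 in WSU-FSCCL (adjusted p = 0.926), and neither passed the threshold. IGHM counts in WSU-FSCCL were 130 over the 2 WT libraries and 0 over the 3 W375* libraries, at least 68.4-fold lower against a floor of 3 counts over the group. IGHD had 47 counts in the WT libraries and 0 in the W375* libraries, a difference that missed the threshold (adjusted p = 0.175 by edgeR's quasi-likelihood test). IGHG4 (ENSG00000211892, chromosome 14, 105620506 to 105626066), a near-identical relative of IGHG1, fell from 251 ± 28.3 (n = 2) to 118 ± 4.02 CPM (n = 3) in WSU-FSCCL. The WSU-FSCCL calls of IGHM and IGHG4 both ended without WT library 1, WT library 2 or W375* library 3. Floors and ratio intervals given here and further on cover counting error only.

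**Figure D1:**
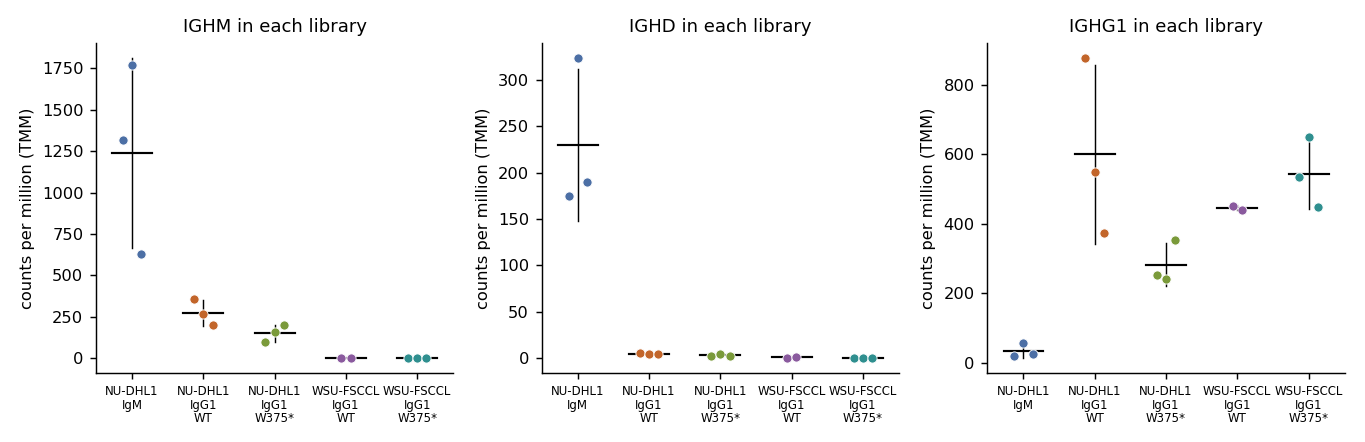
Each point is 1 library, with the level of IGHM, IGHD or IGHG1 in TMM-scaled CPM on the vertical axis and the 5 groups on the horizontal axis; bars are group means with 1 SD. IGHM averaged 1239 in NU-DHL1 IgM and 274 in IgG1 WT, and IGHG1 averaged 33.4 and 599 in those groups.

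Comparing IgG1 WT with IgM cells of NU-DHL1, which asks what goes with the receptor class, found genes on in IgG1 WT that were silent in the IgM cells. Receptor class was not separated from clone or culture in these libraries. EHD3, an adaptor of endocytic recycling, ABCG1, a cholesterol exporter, MYEF2, a transcriptional repressor, and SVIP, an inhibitor of endoplasmic reticulum protein degradation, had 0 counts in all 3 IgM libraries. DTX3, a Deltex ubiquitin ligase, and IFI44L, an interferon-induced gene, rose from near 0 to 20.4 ± 5.3 and 96.4 ± 34.2 CPM (n = 3). Among protein-coding genes that met the naming rule, which leaves out IGHD, the largest falls were in OTOF, a calcium sensor of vesicle fusion, SPRY2, a feedback inhibitor of ERK signalling, and SPP1, the secreted protein osteopontin. DPYSL2, a microtubule regulator, RAB3C, a small GTPase of vesicles, and KCNN4, a calcium-activated potassium channel, also fell.

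EHD3 (ENSG00000013016, GRCh38 chromosome 2, 31234337 to 31269447) reached 17.7 ± 4.82 CPM in IgG1 WT (n = 3), at least 573-fold higher, and ABCG1 (ENSG00000160179, chromosome 21, 42199689 to 42297244) reached 22.1 ± 11.8 CPM, at least 695-fold higher. MYEF2 rose at least 378-fold and SVIP at least 338-fold. The log2 fold changes were 8.87 for DTX3 (ENSG00000178498, chromosome 12, 57604622 to 57609804) and 7.48 for IFI44L (ENSG00000137959, chromosome 1, 78619922 to 78646145). They were -4.75 for OTOF (ENSG00000115155, chromosome 2, 26457203 to 26558698), -3.40 for SPRY2, -3.28 for SPP1, -2.97 for DPYSL2, -2.78 for RAB3C and -2.70 for KCNN4. EHD3, SVIP and DTX3 had the lowest adjusted p in this group of 12 genes (0.000141, edgeR quasi-likelihood, Benjamini-Hochberg), and SPP1 the highest (0.0325).

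Of 15818 genes tested, 426 differed between IgG1 WT and IgM at an adjusted p under 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg), 301 higher and 125 lower, and 370 of them by a log2 fold change of at least 1. Values of the 2 groups did not overlap in any of the 426 genes, and did not overlap in 22.6% of all genes tested, against 10% by chance for 3 libraries against 3. DESeq2 called 1332 genes in the same libraries. The count was 225 without IgM library 1, 168 without IgM library 3, 168 without IgG1 WT library 1, 145 without IgG1 WT library 2 and 818 without IgG1 WT library 3. Of 24 named genes called here, 11 lost their call without IgG1 WT library 1, 9 without IgG1 WT library 2, 8 without IgM library 1, 8 without IgM library 3, 3 without IgM library 2 and 1 without IgG1 WT library 3, SPP1, OTOF, DPYSL2, SCD and FADS2 among those lost without IgG1 WT library 1 or 2.

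Genes of the interferon response were higher in IgG1 WT cells as a group, with 38 of 40 members above their level in IgM cells and a median log2 fold change of 1.51. IFI44L, GBP4, a guanylate-binding protein, and IFI44 led the list. GBP4 rose from 0.0414 ± 0.036 to 5.76 ± 3.75 CPM and IFI44 from 0.199 ± 0.183 to 20.6 ± 9.1 CPM (n = 3). Across all genes tested 20 members passed the threshold, all upward, and 33 passed when adjusted over the list alone, 32 up and 1 down. Camera placed the list above other genes (adjusted p = 1.03e-25, Benjamini-Hochberg over the lists), but adjusted p = 0.297 with an estimated correlation, and fry gave an adjusted p of 0.00731. IFI44L and IFI44 lost their calls without IgM library 1 or IgG1 WT library 1, and IFI44 also without IgM library 3.

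Genes of cholesterol and fatty acid synthesis were lower in IgG1 WT cells in all 33 members tested, with a median log2 fold change of -1.18. SCD, the stearoyl desaturase, ACSS2, an acetyl-CoA synthetase, and FADS2, a fatty acid desaturase, had the largest falls among members past the threshold, with log2 fold changes of -2.48, -2.23 and -1.94. Over all genes tested 4 members passed, all downward, and 28 passed adjusted over the list alone. Camera's adjusted p was 1.58e-20, but adjusted p = 0.690 with an estimated correlation. SCD and FADS2 lost their calls without IgG1 WT library 1 or 2 and without IgM library 1, 2 or 3, while ACSS2 kept its call without each library. Proliferation genes moved in the same libraries: the mean log2 CPM of the G2/M list was 1.82 and 2.50 in IgG1 WT libraries 1 and 2, against 5.90 in library 3 and 4.95 to 7.05 in the IgM libraries. The same 2 libraries had 6.72% and 5.99% of their counts on mitochondrial genes, against 4.07 to 4.75% in the other NU-DHL1 libraries. The median of the cholesterol list was -0.58 with the G2/M level as a covariate and -0.58 without IgG1 WT libraries 1 and 2, alternatives added after the data were seen.

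Cell cycle, amino acid and translation genes also leaned one way as lists between IgG1 WT and IgM. All 32 G2/M and all 30 S phase genes were lower in IgG1 WT, with median log2 fold changes of -1.86 and -1.60. Of these, 0 passed in edgeR or DESeq2 over all genes and 0 adjusted over the list alone, and 0 G2/M and 3 S phase genes had an unadjusted p under 0.05 in edgeR. All 26 targets of the amino acid response factor ATF4 were lower (median -0.75), with 0 called by edgeR over all genes, 2 by DESeq2, 1 adjusted over the list alone and 11 at an unadjusted p under 0.05. Of 40 cytosolic ribosomal protein genes 38 were higher (median 0.27), with 0 called by edgeR over all genes or adjusted over the list alone, 2 by DESeq2 and 12 at an unadjusted p under 0.05. Camera's adjusted p was 1.78e-12 for G2/M, 1.09e-08 for S phase, 3.54e-06 for ATF4 targets and 2.99e-05 for ribosomal proteins, but adjusted p = 0.690 with an estimated correlation for the first 3 lists and 0.694 for the last. Weaker camera calls were glycolysis and hypoxia (median -0.31, adjusted p = 0.00513, 0.690 with an estimated correlation), mitochondrially encoded mRNAs (median 0.25, adjusted p = 0.038, 0.694 with an estimated correlation) and MYC targets (median -0.19, adjusted p = 0.0498, 0.766 with an estimated correlation). With the G2/M level as a covariate the camera calls of the S phase, ATF4, ribosomal protein and mitochondrial mRNA lists all ended. The call of the G2/M list ended too, but this was fixed in advance, since the covariate is the mean of that list.

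In the glycolysis list BNIP3, a mitophagy receptor, rose and SLC16A3, a lactate exporter, fell, with log2 fold changes of 2.04 and -0.87, and 1 member was higher and 6 lower adjusted over the list alone. Of the 13 mitochondrial mRNAs and 40 MYC targets 0 were called by edgeR over all genes or adjusted over the list alone, 0 and 1 by DESeq2, and 3 and 4 had an unadjusted p under 0.05. The germinal centre list did not pass (camera adjusted p = 0.213, median 0.04), yet 7 of its 32 members rose over all genes tested, and 8 passed upward and 3 downward adjusted over the list alone. Among them MME, the CD10 peptidase, rose from 0.0414 ± 0.036 to 3.4 ± 0.698 CPM and GCSAM, a signalling adaptor of germinal centre cells, from 0.279 ± 0.142 to 2.43 ± 0.485 CPM (n = 3). The list of B cell receptor signalling components did not pass either (adjusted p = 0.875, median -0.10, mean 0.32), with 2 members up and 1 down, and 5 up and 4 down adjusted over the list alone. Of 9 lists called, MYC targets were lost without IgM library 1 or 3 or IgG1 WT library 1 or 2, mitochondrial mRNAs without IgM library 2 or 3 or IgG1 WT library 1 or 2, glycolysis without IgM library 2 and ribosomal proteins without IgG1 WT library 1, and 14 lists were called without IgM library 2. BNIP3, SLC16A3 and GCSAM lost their calls without IgG1 WT library 1 or 2, BNIP3 and GCSAM also without IgM library 1 or 3, GCSAM without IgM library 2 and MME without IgM library 3. Myeloid marker genes averaged 0.91 ± 0.145 log2 CPM in IgG1 WT and 0.00434 ± 0.44 in IgM (n = 3) and missed the threshold (camera adjusted p = 0.0674), but passed without IgM library 1 or 3 or IgG1 WT library 1.

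**Figure D2:**
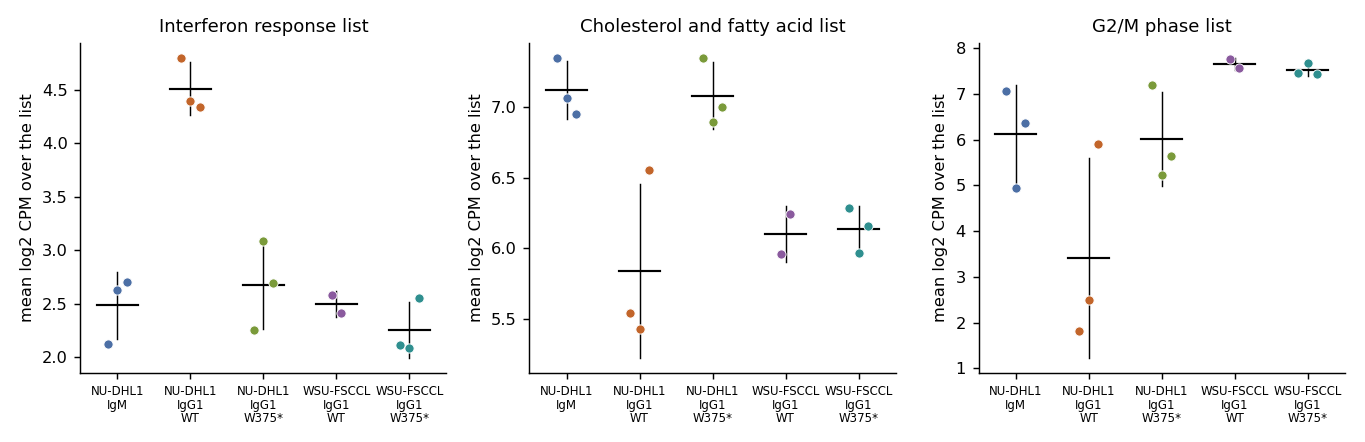
Each point is 1 library, with the mean log2 CPM over the interferon response, the cholesterol and fatty acid synthesis, or the G2/M list on the vertical axis and the 5 groups on the horizontal axis; bars are group means with 1 SD. The interferon list averaged 2.49 in NU-DHL1 IgM, 4.51 in IgG1 WT and 2.68 in IgG1 W375*, and the G2/M list was lowest in IgG1 WT libraries 1 (1.82) and 2 (2.50).

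W375* cells of NU-DHL1, which ask what the tail of the IgG1 receptor contributes, had lower interferon genes than IgG1 WT cells. Several genes that were lower in IgG1 WT than in IgM cells were higher in W375* cells. The labels give 15 weeks of culture after prime editing for the W375* groups only. The stop codon was therefore not separated from editing, clone or culture in either line. SPRY2, RAB3C and ACSS2, which were lower in IgG1 WT than in IgM cells, were higher in W375* than in IgG1 WT cells. So were INPP5J, a phosphoinositide phosphatase, and SLC16A14, an orphan transporter. EHD3 fell back from 17.7 ± 4.82 to 0.65 ± 0.206 CPM (n = 3). ENPP4, a nucleotide phosphodiesterase, OAS1, IFIT2 and MX2, antiviral interferon-induced genes, and CNR2, the cannabinoid receptor of B cells, fell with it.

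SPRY2 (ENSG00000136158, GRCh38 chromosome 13, 80335976 to 80340951) rose by 2.75, INPP5J by 2.66, RAB3C by 2.47, ACSS2 by 1.99 and SLC16A14 by 1.29 on the log2 scale. The log2 fold changes were -4.79 for EHD3, -4.47 for ENPP4 (ENSG00000001561, chromosome 6, 46129993 to 46146699), -3.73 for OAS1 (ENSG00000089127, chromosome 12, 112906777 to 112933222), -3.60 for CNR2, -3.44 for IFIT2 and -3.02 for MX2. Adjusted p was lowest for EHD3 and CNR2 (0.0094, edgeR quasi-likelihood, Benjamini-Hochberg) and highest for MX2 (0.049).

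In all, 43 of 15818 genes passed an adjusted p under 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg), 6 higher and 37 lower in W375*, all by a log2 fold change of at least 1 and all without overlap between groups. No overlap was seen in 18.2% of all genes, against 10% by chance, and DESeq2 called 477 genes. Without IgG1 WT library 1 edgeR called 0 genes, with 1032 at an unadjusted p under 0.05, while DESeq2 called 198 and limma-voom 15. The count was 7 without IgG1 WT library 2, 248 without IgG1 WT library 3, 9 without W375* library 1, 13 without W375* library 2 and 15 without W375* library 3. All 13 named genes lost their call without IgG1 WT library 1, and 10 without IgG1 WT library 2, 9 without W375* library 1, 9 without W375* library 2 and 11 without W375* library 3. EHD3 and CNR2 lost theirs only without IgG1 WT library 1.

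Interferon response genes were lower in NU-DHL1 W375* than in IgG1 WT cells, with 38 of 40 members down and a median log2 fold change of -1.43, and returned to 2.68 ± 0.417 mean log2 CPM, near the 2.49 ± 0.314 of IgM cells (n = 3). Among members past the threshold, IFI27, HERC5, the ligase of the ubiquitin-like protein ISG15, and OAS1 had the largest falls. IFI44L and IFI44 missed it (edgeR adjusted p = 0.0811 and 0.0682). IFI27 had 212 counts in the IgG1 WT libraries and 3 in the W375* libraries, a ratio of 76.2 with a counting interval of 25.7 to 373. Over all genes tested 10 members were lower and 0 higher in edgeR, and 30 were lower and 1 higher adjusted over the list alone. Camera's adjusted p was 7.16e-31 (Benjamini-Hochberg over the lists), but adjusted p = 0.189 with an estimated correlation, and fry gave an adjusted p of 0.0089. All 33 cholesterol and fatty acid synthesis genes were higher in W375* (median 1.11, camera adjusted p = 1.02e-24), 1 of them (ACSS2) over all genes and 29 adjusted over the list alone, but adjusted p = 0.610 with an estimated correlation. Their median was 0.49 with the G2/M level as a covariate and 0.50 without IgG1 WT libraries 1 and 2.

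Proliferation and translation genes leaned back as lists by camera at the preset correlation, with 0 members called by edgeR over all genes. All 32 G2/M and 30 S phase genes were higher in W375* (medians 1.70 and 1.54, camera adjusted p = 1.26e-14 and 4.56e-12), 38 of 40 ribosomal protein genes were lower (median -0.30, adjusted p = 3.48e-07) and 39 of 40 MYC targets higher (median 0.27, adjusted p = 3.24e-05). ATF4 targets (median 0.63, adjusted p = 0.00028) and nuclear genes of oxidative phosphorylation (median 0.22, adjusted p = 0.00184) were higher. Heavy chain constant genes (median -0.84, adjusted p = 0.00182), MHC class I genes (median -0.33, adjusted p = 0.013), p53 targets (median -0.17, adjusted p = 0.0113) and 6 myeloid marker genes (median -1.30, adjusted p = 0.00337) were lower. All 10 of these lists had an adjusted p = 0.610 with an estimated correlation. Over all genes edgeR called 0 members of each; DESeq2 called 0 to 2, and 0 to 7 per list had an unadjusted p under 0.05. Adjusted over the list alone, 1 heavy chain gene, 3 p53 targets and 3 myeloid genes were lower and 0 members of the other 7 lists passed.

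The comparison shares the IgG1 WT libraries with class switching, and G2/M genes averaged 5.23 to 7.19 log2 CPM in the W375* libraries against 1.82 and 2.50 in IgG1 WT libraries 1 and 2. MHC class I genes lost their camera call without IgG1 WT library 1 or W375* library 1, p53 targets without IgG1 WT library 1 or W375* library 2, and ATF4 targets and oxidative phosphorylation without W375* library 1. With the G2/M level as a covariate, an alternative added after the data were seen, 7 of 33 lists were called in place of 12, and 24 genes in place of 43. The lists that lost their call were G2/M, S phase, ribosomal protein, ATF4, oxidative phosphorylation, heavy chain constant, MHC class I and p53 genes. For the G2/M list this was fixed in advance, since the covariate is its own mean level.

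Most genes lower in W375* than in IgG1 WT cells, 33 of 37, were higher in IgG1 WT than in IgM cells. These were only 33 of the 301 genes higher in IgG1 WT. Neither class switching nor the stop codon was separated from clone or culture. In all, 38 genes were called in the opposite direction. EHD3 was among those higher in IgG1 WT than in IgM and W375* cells. SPRY2, RAB3C and ACSS2 were among 5 that were lower there than in those groups. Independent lists of these sizes would share 0.704 and 0.0474 genes, and 30 simulations of unchanged groups around shared IgG1 WT libraries gave 0.0667 on average and at most 1. Those simulations called only 0.1 class-switch and 0.167 W375* genes on average. Their overlap was therefore bound to be near 0 and cannot say how many of the 38 genes came from shared libraries. The covariance of the fold changes was -0.56, against -0.13 in the simulation, a difference of -0.43. With 3 shared IgG1 WT libraries no split kept 2 in each part, so some of the excess may come from the shared libraries. The overlap was 0, 5 and 227 genes without IgG1 WT library 1, 2 and 3, and 8, 11 and 10 without W375* library 1, 2 and 3, against 379 in DESeq2 with all libraries.

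Part of the class-switch profile stayed in W375* cells when they were set beside IgM cells, a comparison that shares no IgG1 WT library. There, 53 of the 426 class-switch genes were called in the same direction. PRKACB, a catalytic subunit of protein kinase A, PDE3B, a cyclic AMP phosphodiesterase, BLK, a Src-family kinase of B cells, DTX3, CD163L1, a scavenger receptor, and KIF21A, a kinesin, were all higher than in IgM cells. PRKACB (ENSG00000142875, GRCh38 chromosome 1, 84078062 to 84238498) stood at 7.68 ± 1.14 CPM in IgM, 133 ± 22.8 in IgG1 WT and 101 ± 4.13 in W375* (n = 3). PDE3B (ENSG00000152270, chromosome 11, 14643723 to 14872044) went from 0.647 ± 0.223 to 15.1 ± 0.749 and 15.3 ± 2.47 CPM. MCAM, an adhesion molecule, and STK24, a protein kinase, were lower than in IgM cells in both IgG1 groups. CTPS2, a CTP synthase, BTNL9, a butyrophilin-like receptor, and PJA1, a ubiquitin ligase, were lower in W375* than in IgM cells but were not called on class switching. BTNL9 stood at 41.9 ± 20.5 CPM in IgM, 31.3 ± 8.97 in IgG1 WT and 4.57 ± 1.99 in W375*, and PJA1 at 16.9 ± 2.7, 15.9 ± 0.785 and 6.63 ± 1.6 (n = 3).

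The log2 fold changes of W375* against IgM were 8.17 for DTX3, 4.53 for PDE3B, 3.69 for PRKACB, 2.99 for CD163L1, 2.82 for BLK and 2.78 for KIF21A, and -3.22 for BTNL9, -3.19 for CTPS2, -1.73 for MCAM, -1.38 for PJA1 and -0.72 for STK24. IGHD (-6.35), IGHM (-3.07) and IGHG1 (3.05) differed in the same directions as on switching. IGHG1 lost its call without IgM library 1 or 3 or W375* library 2 or 3, and IGHM without W375* library 2. The lowest adjusted p was that of PRKACB (5.19e-05, edgeR quasi-likelihood, Benjamini-Hochberg). BLK was lower in W375* than in IgG1 WT cells in group means, at 12.4 ± 4.42 against 34.5 ± 4.39 CPM (n = 3), and MCAM was 70.0 ± 7.77 in IgM, 26.3 ± 7.11 in IgG1 WT and 21.6 ± 8.19 in W375*.

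In total 59 genes passed between W375* and IgM (edgeR quasi-likelihood, adjusted p under 0.05), 51 higher and 8 lower, 57 of them by a log2 fold change of at least 1, and DESeq2 called 207. Groups did not overlap in any of the 59 genes and in 8.88% of all genes, against 10% by chance. Of the 59 genes, 53 were called in the same direction on class switching (49 up, 4 down), where independent lists would share 0.97 and 0.0632 and the simulation of unchanged groups around shared IgM libraries gave 0.0333. Unchanged groups give few calls to overlap, so this simulated value too was bound to be low. The covariance of the fold changes was 0.44 against 0.13 in that simulation, a difference of 0.31, and part of the excess may come from the 3 shared IgM libraries. The count was 31 without IgM library 1, 28 without IgM library 3 and 30 without W375* library 2, and of 14 named genes 4, 3 and 5 lost their call without IgM library 1, 2 and 3 and 4, 5 and 3 without W375* library 1, 2 and 3, MCAM, PJA1 and STK24 most often.

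Gene groups hardly separated W375* from IgM cells: 0 of 33 lists with enough members passed camera, and the median log2 fold changes were 0.04 for the interferon, -0.10 for the cholesterol and -0.11 for the G2/M list. Camera gave 6 lists an unadjusted p under 0.05, glycolysis, ATF4 and p53 target genes among them, and camera with an estimated correlation and fry called 0. Without IgM library 1, 2 or 3 camera called 8, 7 and 5 lists, and without W375* library 1, 2 or 3 it called 7, 1 and 1.

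In WSU-FSCCL, W375* cells can be compared with WT only within IgG1 cells. MKRN3, an imprinted ubiquitin ligase, was nearly silent in WT and on in W375* cells. NECTIN1, an adhesion receptor, BASP1, a membrane-bound signalling protein, VAT1L, TRIM72, a membrane-repair protein, and PLXDC1 were higher in W375* cells. FAM129C, a B cell gene of the Niban family, fell from 414 ± 64 CPM (n = 2) to 11.8 ± 4.05 CPM (n = 3). PLEKHG1, DEPP1, a FOXO target, GIMAP4, a lymphocyte GTPase, and DST, a cytoskeletal linker, fell too, as did AC119396.1, annotated as protein-coding.

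FAM129C (ENSG00000167483, GRCh38 chromosome 19, 17523301 to 17553839) had a log2 fold change of -5.13, with the lowest adjusted p (0.00286, edgeR quasi-likelihood, Benjamini-Hochberg). MKRN3 (ENSG00000179455, chromosome 15, 23565674 to 23630075) had 2 counts in the WT and 2073 in the W375* libraries, a ratio of 657 with a counting interval of 182 to 5426. NECTIN1 (ENSG00000110400, chromosome 11, 119623408 to 119729084) rose from 12.6 ± 0.827 to 114 ± 23.4 CPM. The log2 fold changes were 5.05 for BASP1, 4.91 for VAT1L, 4.20 for TRIM72 and 3.24 for PLXDC1, and -3.54 for PLEKHG1, -2.97 for DEPP1, -2.90 for GIMAP4, -2.89 for DST and -2.58 for AC119396.1.

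In total 90 of 16061 genes passed (edgeR quasi-likelihood, adjusted p under 0.05), 46 higher and 44 lower, 89 by a log2 fold change of at least 1, and DESeq2 called 435. Groups did not overlap in any of the 90 genes and in 24.0% of all genes, against 20% by chance for 2 libraries against 3. The count was 4 without WT library 1, 4 without WT library 2, 237 without W375* library 1 and 4 without W375* library 3; with 1 WT library left, that library is assumed to vary like the W375* group. Of 21 named genes 19 lost their call in each of the 3 settings with 4 calls left, among them DEPP1, CD22 and TNF, and DST without W375* library 2. FAM129C kept its call without each library in turn. Light chain segments also differed between these groups, as given further on, and clone was not separated from the stop codon.

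Signalling genes of the B cell receptor were higher in WSU-FSCCL W375* cells, with 30 of 37 components above WT and a median log2 fold change of 0.44. CD22, an inhibitory co-receptor of B cells, rose from 7.09 ± 0.158 (n = 2) to 60.5 ± 15.7 CPM (n = 3). The immediate early list was higher too (median 0.38), with TNF up from 0.517 ± 0.127 to 7.13 ± 2.44 CPM and ZFP36L1, a decay factor for AU-rich messages, from 38.1 ± 3.29 to 137 ± 30.3 CPM. SPRY4, a feedback inhibitor in the MAPK list (median 0.22), rose by 3.74 on the log2 scale, and BASP1 led the germinal centre list (median 0.33).

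Over all genes edgeR called 1 receptor component, 2 immediate early, 1 MAPK and 1 germinal centre gene, all upward; adjusted over the list alone, 8 receptor components rose and 1 fell, 5 immediate early genes rose and 1 fell, 3 MAPK genes rose, and 8 germinal centre genes rose and 2 fell. Camera's adjusted p was 3.74e-07 for receptor components, 3.91e-05 for immediate early genes, 0.000145 for MAPK genes and 0.000243 for germinal centre genes, but adjusted p = 0.507, 0.507, 0.510 and 0.507 with an estimated correlation. These 4 lists kept their camera call without each library in turn, whereas CD22, TNF, ZFP36L1, SPRY4 and BASP1 lost theirs without WT library 1, WT library 2 or W375* library 3.

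FOXO1 targets went the other way, in part. TRIB2, a pseudokinase, fell from 5.67 ± 0.758 (n = 2) to 0.772 ± 0.187 CPM (n = 3), while the list as a whole had a median of only -0.05 (camera adjusted p = 0.0448), with 2 members down over all genes, and 3 down and 1 up adjusted over the list alone. Of the dark zone list (median -0.27, adjusted p = 0.00141) TFDP2, a partner of E2F factors, fell by 0.94 on the log2 scale, 1 member being lower over all genes and 2 adjusted over the list alone. The list of heavy chain constant genes was lower as well (median -0.72, adjusted p = 0.000243), with IGHM and IGHG4 called and 3 members lower adjusted over the list alone. The FOXO1 call ended without WT library 1 or W375* library 1 or 3, and adjusted p = 0.667 with an estimated correlation for FOXO1 targets and 0.507 for the other lists. TRIB2 and TFDP2 lost their calls without WT library 1, WT library 2 or W375* library 3.

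Metabolic and other groups shifted by small amounts in WSU-FSCCL W375* cells. Ribosomal protein genes were higher in 40 of 40 members (median 0.18, camera adjusted p = 9.75e-05), as were glycolysis genes (median 0.41, adjusted p = 0.0106), oxidative phosphorylation genes (median 0.15, adjusted p = 0.00806), PI3K-mTOR components (median 0.15, adjusted p = 0.0448) and 4 T cell marker genes (median 0.65, adjusted p = 0.0166). MHC class II genes (median -0.22, adjusted p = 0.000907), G2/M genes (median -0.16, adjusted p = 0.00404) and interferon genes (median -0.20, adjusted p = 0.0143) were lower. None of the 8 passed with an estimated correlation, the values being adjusted p = 0.507 for MHC class II, 0.556 for PI3K-mTOR and T cell markers and 0.687 for the rest. Over all genes edgeR called 0 members of each list; DESeq2 called 0 to 2, and 0 to 7 per list had an unadjusted p under 0.05. Adjusted over the list alone, 2 T cell marker genes were higher and 0 members of the other lists passed.

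Of these 8 lists the camera call of PI3K-mTOR components ended without WT library 1, WT library 2, W375* library 2 or W375* library 3, that of interferon genes without WT library 1 or W375* library 1 or 2, and that of G2/M genes without WT library 1 or W375* library 3. Glycolysis and ribosomal protein genes lost theirs without W375* library 2, oxidative phosphorylation genes without W375* library 1, and T cell markers without W375* library 3.

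CTPS2, INPP5J and OVAAL were the 3 genes called in the same direction between W375* and IgG1 WT in both lines. CTPS2 (ENSG00000047230, GRCh38 chromosome X, 16588003 to 16712936) fell from 9.92 ± 1.98 to 1.78 ± 0.302 CPM in NU-DHL1 (n = 3) and from 7.29 ± 0.194 (n = 2) to 0.801 ± 0.224 CPM (n = 3) in WSU-FSCCL, with log2 fold changes of -2.52 (adjusted p = 0.0094) and -3.18 (adjusted p = 0.0198, edgeR quasi-likelihood, Benjamini-Hochberg). INPP5J (ENSG00000185133, chromosome 22, 31122731 to 31134696) rose by 2.66 and 2.42 on the log2 scale. OVAAL, a long noncoding RNA (ENSG00000236719, chromosome 1, 180552749 to 180566520), rose by 5.45 and 1.96, from 0.0472 ± 0.0448 CPM in NU-DHL1 IgG1 WT, which lay under the 2.81 ± 0.901 CPM of IgM cells. OVAAL stood at 20.3 ± 4.55 (n = 2) and 79.6 ± 17.2 CPM (n = 3) in WSU-FSCCL. Its NU-DHL1 counts therefore include any WSU-FSCCL transcripts in the W375* libraries, described further on. Library 3, which held the fewest of these, had 2.36 CPM. Of the genes near CTPS2, SYAP1 had log2 fold changes of -0.07 and -0.14, TXLNG of 0.13 and -0.06 and REPS2 of -1.12 and -0.43, none of them called.

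**Figure D3:**
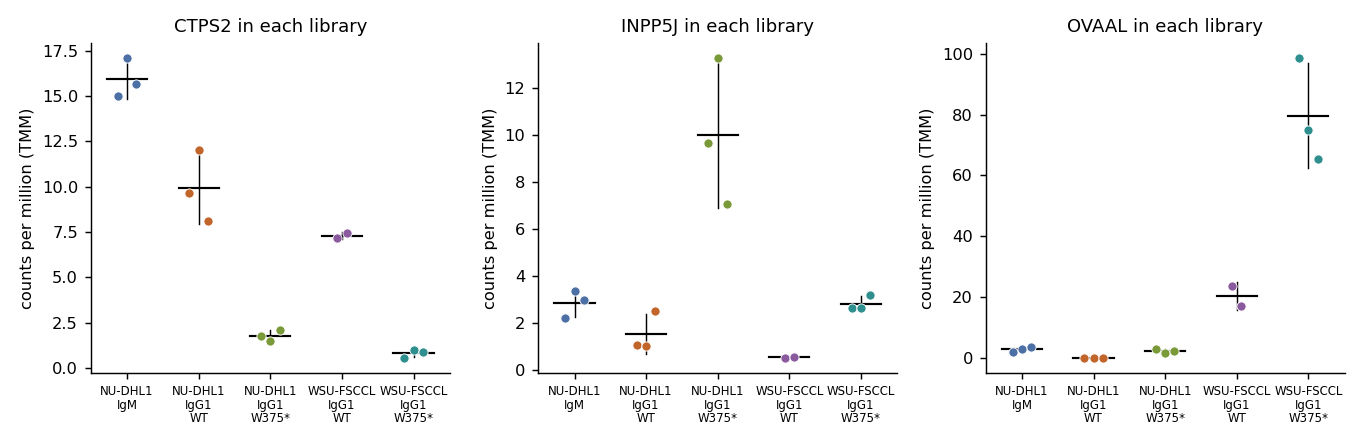
Each point is 1 library, with the level of CTPS2, INPP5J or OVAAL in TMM-scaled CPM on the vertical axis and the 5 groups on the horizontal axis; bars are group means with 1 SD. CTPS2 averaged 9.92 and 1.78 in NU-DHL1 IgG1 WT and W375*, and 7.29 and 0.801 in the same groups of WSU-FSCCL.

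Among 14087 genes tested in both lines, independent lists would share 0.0114 genes upward and 0.0515 downward, against 2 and 1 seen (Fisher's exact test, one-sided, p = 4.98e-05 and 0.0503). OVAAL is 1 of the 2 upward genes and belongs to the set of 5 up-called genes tested next. Any WSU-FSCCL transcripts in the NU-DHL1 W375* libraries would make the lines look alike there, so the upward tests do not exclude that source. Genes called in NU-DHL1 leaned the same way in WSU-FSCCL as sets, 5 up-called genes having a median log2 fold change of 1.14 (camera adjusted p = 0.000137) and 29 down-called genes of -0.29 (camera adjusted p = 8.9e-05). Neither set passed camera with an estimated correlation (adjusted p = 0.0827 for both, Benjamini-Hochberg over 4 sets). In the reverse test 32 genes called up in WSU-FSCCL were higher in NU-DHL1 (median 0.36, camera adjusted p = 6.08e-05, but adjusted p = 0.185 with an estimated correlation). The 25 genes called down were not shown to be lower (median -0.08, camera adjusted p = 0.119, and adjusted p = 0.409 with an estimated correlation). Over all genes the 2 effects were nearly unrelated, with Pearson's r of 0.0686 across genes, which are not independent replicates. With plain differences of mean log2 CPM in WSU-FSCCL r was 0.0765, and 7 of the 10 splits of its libraries into 2 and 3 gave an r as large in absolute value (exact p = 0.7). The 2 lines shared 0 genes without NU-DHL1 IgG1 WT library 1, WSU-FSCCL WT library 1 or 2 or WSU-FSCCL W375* library 3, 1 gene without NU-DHL1 IgG1 WT library 2 or W375* library 3, and 5 without NU-DHL1 IgG1 WT library 3, while DESeq2 shared 25.

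Of the called class-switch genes, 216 of 339 tested in WSU-FSCCL (63.7%) had the opposite sign in W375* cells there, a share without a no-change value to set it against. Over all 14087 genes the relation was weak, with Pearson's r of -0.0664. The 227 called genes higher in NU-DHL1 IgG1 WT than in IgM were lower as a set (median -0.15, camera adjusted p = 0.00049, but adjusted p = 0.105 with an estimated correlation). The 112 called genes lower in IgG1 WT were not shown to be higher (median 0.12, camera adjusted p = 0.0887). Only 7 genes were called in opposite and 3 in the same direction, where independent lists would share 0.403 and 0.254, and 0.516 and 0.199.

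The difference between W375* and WT cells was unlike between the lines for some genes, in a test of that contrast itself. Stop codon, editing, clone and culture were not separated in either line. ENDOD1, an endonuclease-like gene, was at 4.6 ± 1.03 CPM (n = 2) in WSU-FSCCL WT and at 0 counts in the 3 W375* libraries, at least 183-fold lower, while NU-DHL1 held 109 ± 14.7 and 122 ± 8.54 CPM (n = 3). ARHGAP39 went from 288 counts in NU-DHL1 IgG1 WT to 0 in W375*, at least 104-fold lower, but was near 0 in IgM cells too, at 0.102 ± 0.0383 CPM (n = 3). It stayed near 4.88 ± 1.51 and 4.24 ± 0.839 CPM in WSU-FSCCL. DUXAP8 and DUXAP9, noncoding copies of one pseudogene family whose reads can be shared, came on in WSU-FSCCL W375*, with 1 against 1320 counts for DUXAP8 (a ratio of 836, interval 150 to 33058) and 0 against 218 for DUXAP9 (at least 46.0-fold higher).

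In total 99 of 18413 genes passed the interaction test (edgeR quasi-likelihood, adjusted p under 0.05), 46 with the higher effect in NU-DHL1 and 53 in WSU-FSCCL, and DESeq2 called 338. The difference of log2 effects was 10.54 for ENDOD1 (ENSG00000149218, GRCh38 chromosome 11, 95089810 to 95132645, adjusted p = 3.04e-06), -9.47 for ARHGAP39 (ENSG00000147799, chromosome 8, 144529179 to 144605816), -9.34 for DUXAP8, -9.17 for DUXAP9 and -8.62 for NBPF3, which belongs to a family of near-identical copies. Fitted values of this size rest on groups at 0 counts and depend on the prior count. IGKV4-1 (10.69), BAHCC1 (10.48) and IGLL1 (9.01) were called because counts appeared in NU-DHL1 W375*, where all 3 are at 0 in the other NU-DHL1 groups and abundant in WSU-FSCCL.

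Without NU-DHL1 IgG1 WT library 1, 2 or 3 the interaction count was 46, 33 and 268, without NU-DHL1 W375* library 1 or 2 it was 51 and 61, without WSU-FSCCL WT library 1 or 2 it was 24 and 19, and without WSU-FSCCL W375* library 2 or 3 it was 55 and 54. IGLL1 lost its call in all of these settings, IGKV4-1 and BAHCC1 in all but that without NU-DHL1 IgG1 WT library 3, and the 3 genes also without WSU-FSCCL W375* library 1. NBPF3 lost its call in all but those without NU-DHL1 IgG1 WT library 1 or 3, and DUXAP8 without either WSU-FSCCL WT library, whereas ENDOD1, ARHGAP39 and DUXAP9 kept theirs.

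Transcripts of WSU-FSCCL were found at a low level in the NU-DHL1 W375* libraries. MAGED1, a melanoma-antigen family gene, BAHCC1 and 15 other genes had at least 50 CPM in every WSU-FSCCL library and at most 0.1 CPM in every NU-DHL1 IgM and IgG1 WT library. Their median level was 1.30% and 1.32% of the WSU-FSCCL level in W375* libraries 1 and 2, with all 17 genes detected, and 0.188% in library 3, with 14 detected. Genes at least 20 times higher in WSU-FSCCL made up 2 of the 43 calls of W375* against IgG1 WT, 9 of the 59 against IgM, all upward, and 24 of the 99 interaction calls. Among all genes tested they were 155 of 15818 in each of these NU-DHL1 comparisons and 1018 of 18413 in the interaction test. These genes were chosen after their values were seen.

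**Figure D4:**
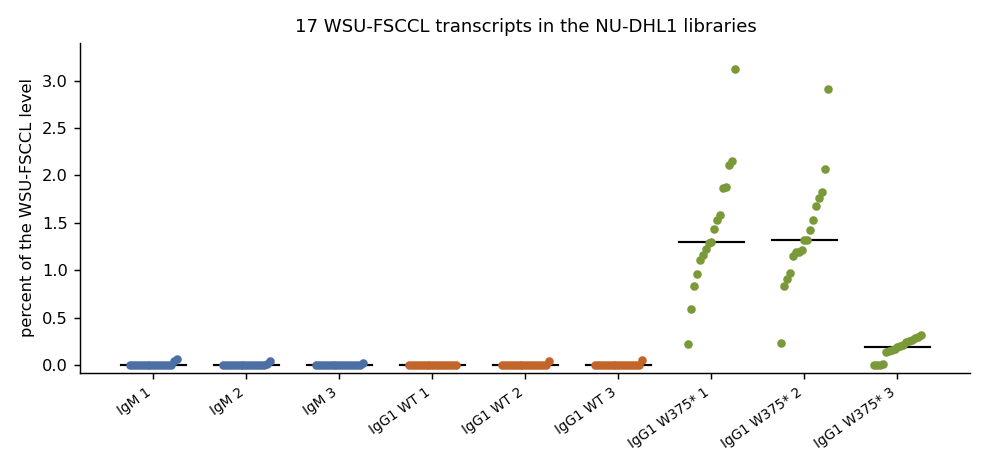
Each point is 1 of 17 genes in 1 NU-DHL1 library (horizontal axis), as a percent of its mean level in the 5 WSU-FSCCL libraries (vertical axis); lines are medians. The medians were 1.30, 1.32 and 0.188 percent in W375* libraries 1, 2 and 3, and 0 in the IgM and IgG1 WT libraries.

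Genes of the long arm of chromosome 13 were lower in both IgG1 groups than in IgM cells of NU-DHL1, a stretch chosen after its values were seen. STK24 averaged 200 ± 4.2 CPM in IgM, 111 ± 4.21 in IgG1 WT and 124 ± 10.4 in W375* (n = 3). SPRY2, in the same stretch, averaged 16.4 ± 5.74, 1.54 ± 0.284 and 10.7 ± 5 CPM (n = 3). Unlike the stretch as a whole, it was much lower in IgG1 WT than in W375* cells. Between 30 and 105 Mb of GRCh38, 124 genes had a median log2 fold change of -0.69 in IgG1 WT (111 lower) and -0.56 in W375* (118 lower) against IgM, and 21 of them were called on class switching. The 59 other genes of the chromosome had medians of -0.06 and 0.01, and the stretch had a median of 0.12 between W375* and IgG1 WT.

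**Figure D5:**
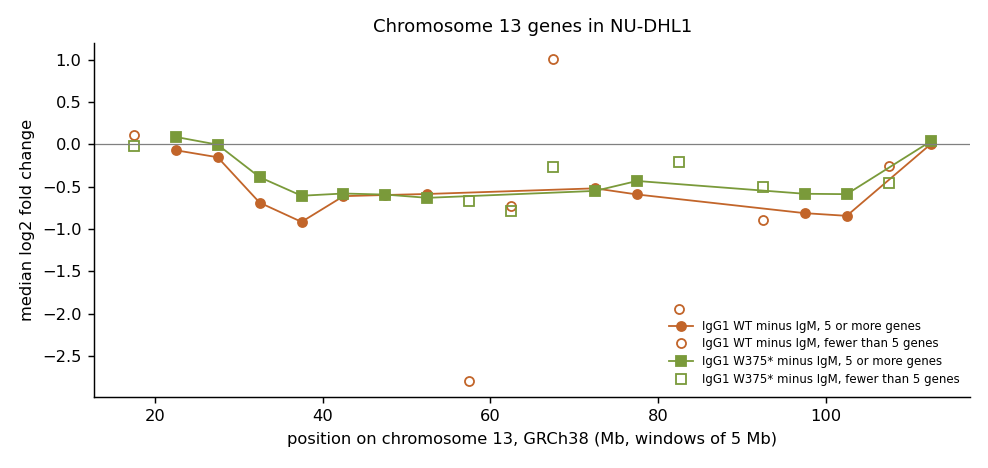
Each point is the median log2 fold change against IgM (vertical axis) of the genes in a window of 5 Mb along chromosome 13 of GRCh38 (horizontal axis), for IgG1 WT (circles) and W375* (squares) in NU-DHL1; open points hold fewer than 5 genes. In 9 of the 12 windows with 5 or more genes both medians lay below -0.3.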

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

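The tests of WSU-FSCCL transcripts in the NU-DHL1 libraries were all chosen after those transcripts had been seen, while the interaction test was planned. The difference between W375* and WT cells was unlike between the lines for 99 genes by the interaction test (edgeR quasi-likelihood). By camera at the preset correlation the same held for 10 gene lists. Stop codon, editing, clone and culture were not separated in either line. The difference of log2 effects, NU-DHL1 minus WSU-FSCCL, was 10.54 for ENDOD1, -9.47 for ARHGAP39, -9.34 for DUXAP8, -9.17 for DUXAP9 and -8.62 for NBPF3. ENDOD1, DUXAP8 and DUXAP9 changed in WSU-FSCCL and ARHGAP39 in NU-DHL1, while NBPF3 missed the threshold in WSU-FSCCL alone and was too low to be tested in NU-DHL1 alone. For IGKV4-1, BAHCC1 and IGLL1 the difference was 10.69, 10.48 and 9.01. Fitted differences of this size rest on groups at or near 0 counts, so they give no size of effect.

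Among lists, camera on the interaction found higher effects in NU-DHL1 for G2/M genes (median difference 1.91), S phase genes (1.45), cholesterol and fatty acid synthesis genes (1.01), dark zone genes (0.47) and ATF4 targets (0.46). Effects were lower in NU-DHL1 for interferon genes (-1.30), ribosomal protein genes (-0.45), receptor signalling components (-0.45), germinal centre genes (-0.41) and p53 targets (-0.30). No list passed with an estimated correlation (adjusted p of 0.260 to 0.755). In edgeR 1 cholesterol gene was higher and 1 receptor component, 2 interferon and 2 germinal centre genes were lower over all genes tested, with 2 cholesterol and 2 germinal centre genes higher and 10 receptor components, 9 interferon genes and 6 germinal centre genes lower adjusted over the list alone. Dark zone genes lost their camera call without NU-DHL1 IgG1 WT library 1 or 2, NU-DHL1 W375* library 1 or WSU-FSCCL W375* library 1, ATF4 targets without NU-DHL1 IgG1 WT library 2, NU-DHL1 W375* library 1, WSU-FSCCL WT library 2 or W375* library 2, p53 targets without NU-DHL1 IgG1 WT library 1, and germinal centre genes without NU-DHL1 W375* library 3. Camera called 16 lists without WSU-FSCCL W375* library 1. G2/M genes were low only in NU-DHL1 IgG1 WT libraries 1 and 2, and without those 2 libraries 15 genes differed between the lines in place of 99.

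IGKV4-1, BAHCC1 and IGLL1, abundant in WSU-FSCCL and at 0 in NU-DHL1 IgM and IgG1 WT, had counts in NU-DHL1 W375* cells, most of all in libraries 1 and 2. A general loss of gene silencing in W375* cells is argued against, since 0 of 31418 genes silent in WSU-FSCCL and in NU-DHL1 IgM and IgG1 WT reached 0.5 CPM in both libraries. Reads crossing evenly between all libraries would reach the IgM and IgG1 WT libraries too. Of 3741 genes abundant in WSU-FSCCL, 23 had fewer counts there than the lowest share seen in W375* library 1 (0.221%) would bring. The 23 include the 17 genes chosen for near silence in those libraries, and the share is the lowest among the 17. For these genes the outcome was fixed in advance. The test is therefore no separate evidence on how reads reached the W375* libraries. A small share of WSU-FSCCL cells or reads in these libraries is in line with 100% of the 17 genes abundant in WSU-FSCCL having counts in both libraries 1 and 2, at medians of 1.30% and 1.32% of the WSU-FSCCL level. Whether the source was cells in culture, RNA or sequencing reads stays open, so calls of genes that rose in NU-DHL1 W375* and are at least 20 times higher in WSU-FSCCL cannot be credited to the stop codon alone.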

How the results depend on the processing

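Chosen only after the data were seen were the G2/M covariate, the fits without 2 libraries of a group and the fit without genes high in WSU-FSCCL. Class-switch genes leaned to the opposite sign in WSU-FSCCL W375* cells (63.7%) under every alternative run, at 60.1 to 64.4%, and at 56.4 to 71.6% with 1 library left out, and IGHM, IGHD and IGHG1 kept their directions on switching. Across the comparisons below, 143 of 249 alternative values were about the same, 71 were weaker and 35 stronger, and the cause was not tested. Counts within a ratio of 1.5 were taken as about the same. The 143 also hold immunoglobulin ratios, the share of opposite signs and the correlation between lines. Those could not be labelled weaker or stronger, so the 143 do not show that most counts held.

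Counts are given in the order class switch, W375* against IgG1 WT, W375* against IgM, WSU-FSCCL and difference between lines, where the reported counts are 426, 43, 59, 90 and 99. DESeq2 called 1332, 477, 207, 435 and 338. Without a filter edgeR called 1840, 1170, 328, 583 and 854, and with a mean CPM of at least 5 it called 176, 17, 26 and 49 in the first 4. All 14 libraries in one fit gave 668, 163 and 119 in the first 3, and only the 6 libraries of the 2 groups gave 21 for W375* against IgM. Limma-trend on log2(FPKM + 1) called 101, 12 and 236 for W375* against IgG1 WT, W375* against IgM and the difference between lines, and limma-voom 89 and 37 for the first pair. The G2/M covariate gave 24 and 118 for W375* against IgG1 WT and against IgM. Without NU-DHL1 IgG1 WT libraries 1 and 2, which leaves 1 library assumed to vary like the other groups, edgeR called 36 genes on class switching, 0 for W375* against IgG1 WT (489 at an unadjusted p under 0.05, 34 in DESeq2, 0 in limma-voom) and 15 between lines. Without NU-DHL1 W375* libraries 1 and 2 it called 0 for W375* against IgG1 WT (836 at an unadjusted p under 0.05, 101 in DESeq2, 0 in limma-voom), 16 against IgM and 24 between lines. Leaving out 1 library gave 145 to 818, 0 to 248, 28 to 52, 4 to 237 and 19 to 268.

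The overlap of 3 genes between lines, CTPS2, INPP5J and OVAAL, was 25 in DESeq2, 0 with a mean CPM of at least 5, 0 to 5 with 1 library left out, and 0 without either pair of libraries. The 38 class-switch genes called in the opposite direction by W375* were 379 in DESeq2, 16 with a mean CPM of at least 5, 0 to 227 with 1 library left out, and 0 without either pair. BAHCC1 turned direction in limma-trend on log2(FPKM + 1), with a difference between lines of -0.074 (limma adjusted p = 0.956) against 10.48 in edgeR.

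Of the lists called by camera (9, 12, 0, 15 and 10 in the same order), camera with an estimated correlation kept 0 in every comparison, and fry called 1, 1, 0, 0 and 0, the 1 being interferon genes in both. With the G2/M covariate 4 lists were called on class switching, 7 for W375* against IgG1 WT and 4 against IgM. For W375* against IgG1 WT 8 of the 12 lists were lost, so some of the 7 were new calls. Without NU-DHL1 IgG1 WT libraries 1 and 2, 4 and 6 were called in the first 2. With 1 library left out the lists were 7 to 14, 12 to 15, 1 to 8, 11 to 18 and 8 to 16.

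Whether replicate numbers pair the samples was left open by the values. Same-numbered deviations correlated at -0.24 to 0.58 in NU-DHL1, where 6 of 9 libraries correlated best with their own number, and at -0.12 and -0.10 in WSU-FSCCL. The replicate block gave 421, 25, 44, 34 and 54 calls, shared 1 gene between lines and 21 opposite to class switching, and called 3 lists for W375* against IgM.

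At this depth and spread few 2-fold changes can be called. On simulated data 8.96% of them were recovered for class switching and for W375* against IgG1 WT, 14.9% for W375* against IgM and 13.4% for WSU-FSCCL. Folds between 2 and 4 were not simulated. Among named genes 345 of 424 alternatives stayed past the threshold on class switching, 152 of 256 for W375* against IgG1 WT, 208 of 266 against IgM, 204 of 290 in WSU-FSCCL and 120 of 177 between lines, and IGHD, EHD3, SVIP, DTX3, PDE3B, PRKACB, FAM129C and ENDOD1 passed under each alternative run for at least 1 comparison.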

Other observations

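Of the tests below, those of the interferon list and of the chromosome 13 stretch as a loss were chosen only after the results were seen, while the splits of the samples and the tests of cell cycle and gene length for chromosome 13 were written before their results. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Of these, 1 split, the real one, gave as many genes in each comparison: 426 on class switching against at most 1 in other splits, 43 for W375* against IgG1 WT against at most 0, and 59 for W375* against IgM against at most 0 (edgeR quasi-likelihood).

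Immunoglobulin light chain segments differed between WSU-FSCCL groups, in values chosen after they were seen. Whether the groups came from the same clone was not tested. Neither these differences nor the 90 genes called in WSU-FSCCL can therefore be credited to the stop codon alone. IGLV3-12 stood at 33.8 and 38.8 CPM in the 2 WT libraries and at 0.873 to 1.02 CPM in W375*, IGLV2-5 at 104 and 111 against 11.1 to 13.4 CPM, and IGLV3-10 at 56.4 and 65.4 against 7.21 to 11.9 CPM, while IGLV3-6 was at 6.12 and 7.09 against 26.6 to 37.1 CPM.

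Interferon response genes were higher in IgG1 WT than in IgM or W375* cells of NU-DHL1, in all 3 libraries. The low cycling of IgG1 WT libraries 1 and 2 is argued against as the whole cause, since the list's median log2 fold change was 1.37 with the G2/M level as a covariate and 1.51 without it, with 16 members called in place of 20. Interferon made by the IgG1 WT cells themselves was not settled: the highest level of any of 22 interferon genes was 0.357 CPM (IFNK, in library 2), and interferon messages can be brief. A hypothesis that stays open is that the intact IgG1 tail may raise interferon signalling, since the list fell back in W375* cells, but separate clones or culture conditions could give the same pattern. In WSU-FSCCL the list had a median of only -0.20 in W375* against WT, and the effect differed between lines by -1.30. A difference of this size between W375* and WT cells is thus not seen in both lines. The lines were not like tests of the tail, since W375* cells were more than 77% of the WSU-FSCCL and more than 95% of the NU-DHL1 population. With no IgM library in WSU-FSCCL, a rise on switching could not be measured there.

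Genes between 30 and 105 Mb of chromosome 13 were lower in both IgG1 groups of NU-DHL1 than in IgM cells, by 0.41 to 0.64 log2 units in each IgG1 library relative to other chromosomes (IgM libraries -0.08 to 0.05). Cell cycle state is argued against, since the chromosome's median relative to other genes was -0.39 with the G2/M level as a covariate and -0.44 without it, and so are gene length and expression level, since 0 of 10000 gene sets matched on these had a median as low (lowest -0.19 against -0.52). A partial loss of 13q in the switched cells is consistent with 9 of 12 windows of 5 Mb with 5 or more genes having both medians under -0.3, with no other such window between them. Under this hypothesis STK24 and other genes there may be lower through copy number rather than receptor class, and a gain in the IgM cells would look the same. No DNA data were available to decide, and the median of these genes was 0.01 between the WSU-FSCCL groups.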
